A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

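Ribosome footprinting and RNA sequencing were carried out on the yeast strain YWG25 of the Sigma1278b background. Per the labels' protocols, cells were grown in YPD at 30 °C to an optical density of about 0.7, treated with 100 µg/ml of cycloheximide, which blocks elongation, harvested by centrifugation and frozen. Extract (50 OD units) was digested with 50 U of RNase I, footprints were isolated on sucrose gradients as single ribosomes, and fragments of about 28 nt were tailed with poly(A), reverse transcribed, circularised and amplified. RNA was selected for poly(A) and fragmented with zinc chloride. The selection was on cellulose for +GLU RNA replicate 1 and all 3 -GLU RNA libraries, and on DynaBeads for +GLU RNA replicates 2 and 3. Subtraction of rRNA is described for all libraries except +GLU RNA replicate 3 and the 3 -GLU RNA libraries. The same treatment text, with cycloheximide, stands in the labels of the libraries titled as lacking the drug, so the absence of the drug and the fast harvest rest on the titles. The duration of starvation, the aligner, its settings, the genome build and the use of strand are not given in the sources used here.

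The authors deposited counts per gene, as whole numbers not normalised, and RPKM values. In 2 of the deposited columns, those of -GLU RNA replicates 1 and 2, the authors' values are called expected counts here because 1 entry in each is not whole. The entry that is not whole, YPR203W, was left out of all libraries, after which all values were whole and no rounding was needed. Its cells may be out of place. Beside counts of 4.81 and 7.98 in these 2 columns, the RPKM cells held 25 and 0. The name does not mean that the other values were estimated. The table held 5704 genes, of which 5703 were analysed. The authors' RPKM values as deposited are counts per kilobase of counted length and per 1e6 counted reads, worked out here from counts and RPKM together. In 93.1% to 93.9% of genes with over 20 counts, the counted length matched, within 0.5 nt, the annotated coding length less 24 nt in 12 libraries and the coding length plus 2 nt in the other 3. Those were +GLU RNA replicate 1, -GLU RNA replicate 3 and -GLU footprint replicate 3. Counts over a region 26 nt longer raise short genes slightly more than long ones, and at which end the 26 nt lie was not worked out. The reference annotation R64 of yeast was used only for gene names, coding lengths and overlaps between coding sequences. It paired 5698 identifiers with names and left 5 unmatched, and no coordinates are given because the authors' build is not stated.

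Libraries were grouped by their titles. Per-library depth set a floor of 3 counts between 0.0981 CPM, in the +GLU library without cycloheximide, and 1.86 CPM, in the -GLU library without cycloheximide titled without the word fast. For the replicated libraries the floor lay between 0.239 and 1.25 CPM. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Replicates of 1 group differed by more than sampling noise in each of the 12 pairs (chi-square per degree of freedom 9.22 to 378), with Spearman correlations across genes of 0.86 to 0.99. A single gene took at most 2.59% of the counts in a replicated library.

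Changes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM factors, after filterByExpr with a minimum count of 10, and p-values were adjusted by the method of Benjamini and Hochberg at 0.05. RNA was tested over 6 libraries, footprints over 6, and translational efficiency over all 12 as the interaction of assay and glucose, that is, the footprint change minus the RNA change. Log2 changes are of -GLU against +GLU, and CPM values are normalised within each fit, so they differ between comparisons. The SE of a change is its size divided by the square root of its F statistic. It is approximate, above all for genes near 0 counts in 1 state. The labels give equal replicate numbers in all groups without saying what a number shares, so the number was not a term of the model. Gene lists (25) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of 1 comparison, and again with an estimated correlation. With the latter, 43 calls were lost. The other 32 of 75 list results kept their side of the threshold, but most of them had not been called. Calls were kept only for gluconeogenesis and the tricarboxylic acid cycle in RNA, and for cytosolic ribosomal proteins and oxidative phosphorylation in footprints. No efficiency list kept its call (lowest camera adjusted p = 0.41). The lists were cytosolic and mitochondrial ribosomal proteins, the proteasome, ribosome biogenesis, translation initiation factors, elongation and termination factors, glycolysis, gluconeogenesis, hexose transporters, the tricarboxylic acid cycle, oxidative phosphorylation, trehalose and glycogen, general stress, chaperones, filamentous growth, protein kinase A, the Snf1 pathway, amino acid biosynthesis, ergosterol, histones, the cell wall, a-cell and alpha-cell markers, haploid-specific genes and meiosis. No gene in the tables matched the list names HXT9, HXT17, COB2, ARG5,6 and LEU2, or the spellings MFALPHA1 and MFALPHA2. The alpha-factor genes had rows under another spelling. The alpha-cell list thus held 5 members, of which 3 passed the count filter. Pairs of near-identical genes, such as ribosomal protein A and B copies, HXT6, histones, TIF1, EFT2, SSB1 and PDC1 with PDC5, are uncertain where reads were divided between copies, as are overlapping genes.

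Groups, tests, lists and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 8 genes with the highest and the 8 with the lowest change among called genes with a mean count of at least 50 whose libraries did not overlap between the states (for efficiency, whose 3 differences by number had 1 sign), up to 4 members of each list with the lowest p, and 16 sentinel genes, 1 of which is not reported here. The single libraries without cycloheximide were compared without a test, naming the 6 highest and 6 lowest genes, as log2 ratios of CPM with a pseudocount of 1 count, for genes with at least 10 counts in each library and 50 in sum. A list's median was set among 10000 random lists of the same size, drawn from the 50 genes nearest in expression. Their 95% intervals are exact binomial intervals on the counts, and that of a correlation is a bootstrap over genes.

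The scripts were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For RNA (5488 genes) 33% and 94% of them were recovered, and 3.79% of calls were false. For footprints (5115 genes) these were 38%, 91% and 5.15%, and for efficiency (5482 genes) 7%, 60% and 4.29%. Camera called 0 of 200 random lists in each. Genes were simulated independently of each other, so this does not test the preset correlation. Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, total counts, TMM within each assay, other filters, a 2-fold minimum, a replicate block, each library left out, the poly(A) material, contrasts from the model over 12 libraries, near-identical pairs summed (61 pairs) and the deposited RPKM with limma-trend. Other alternatives were added after the data were seen and are named with their results. The planned comparison of footprints in 5' leaders was not run because the tables do not count leaders apart. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.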

Results

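Ribosome footprints and RNA were sequenced from YWG25, a budding yeast strain of the Sigma1278b background, which can switch to filamentous growth. Cells were grown to mid-exponential phase in YPD, a rich medium with glucose, and were sampled with glucose (+GLU) or without it (-GLU). The series asks how translation adapts to glucose starvation, and its title names protein kinase A, the kinase that relays glucose signals. Ribosome footprints are the mRNA fragments of about 28 nt that a ribosome shields from RNase I, so their number per gene follows the number of ribosomes on its mRNA. The 15 libraries comprised 3 footprint and 3 RNA libraries for each glucose state, prepared with the translation inhibitor cycloheximide, and 3 single footprint libraries titled as lacking the drug. The +GLU footprint libraries held 4159880, 8680468 and 6509688 counts in replicates 1, 2 and 3, and the -GLU footprint libraries 7921427, 2462250 and 2391712. The +GLU RNA libraries held 12560502, 2840314 and 2423486 counts and the -GLU RNA libraries 11586943, 12480932 and 10591879. Without cycloheximide, the fast-harvest libraries held 30575562 counts with glucose and 8570783 without, and the other library without glucose held 1610986. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

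The first comparison asked which mRNAs differed in abundance between the glucose states. Transcripts of ribosome production fell together without glucose. Of 136 cytosolic ribosomal protein genes, 135 fell and 0 rose, with a median log2 change of -3.63 (camera adjusted p = 1.39e-48, adjusted p = 0.29 with an estimated correlation). In -GLU RNA replicate 3, 131 of 138 of these transcripts lay below both other -GLU replicates, by a median log2 difference of -0.71. RPS22A (YJL190C), of the small ribosomal subunit, went from 1781 ± 364 normalised counts per 1e6 counts (CPM) with glucose to 53.8 ± 14.8 without (mean ± SD, n = 3 each). RPS31 (YLR167W), a ribosomal protein made as a fusion with ubiquitin, went from 7186 ± 3093 to 242 ± 50.4 CPM. All 66 ribosome biogenesis genes fell, by a median of -2.35 (camera adjusted p = 1.44e-16, adjusted p = 0.36 with an estimated correlation), among them the RNA helicase gene DBP2 at -5.62 ± 0.50 (log2 change ± SE). In -GLU RNA replicate 3, 65 of these 66 lay below both others, by a median of -1.52. Translation initiation factors fell in 23 of 26 cases and rose in 0 (median -1.40, camera adjusted p = 7.96e-06, adjusted p = 0.29 with an estimated correlation). Elongation and termination factors fell in 11 of 12 and rose in 0 (median -1.76, camera adjusted p = 7.36e-04, adjusted p = 0.29 with an estimated correlation). Below both other replicates in -GLU RNA replicate 3 were 23 of 26 initiation factors (median -0.55) and 9 of 12 elongation and termination factors (median -0.43).

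Biosynthetic genes fell as well. Amino acid biosynthesis had 41 genes down and 1 up of 58 (median -1.25, camera adjusted p = 2.71e-07, adjusted p = 0.33 with an estimated correlation), with ARO4, of aromatic amino acid synthesis, at -4.08 ± 0.39. Ergosterol biosynthesis had 19 down and 1 up of 23 (median -1.36, camera adjusted p = 3.11e-04, adjusted p = 0.36 with an estimated correlation), with the squalene epoxidase gene ERG1 at -3.02 ± 0.37, and 18 of 23 lay below both other replicates in -GLU RNA replicate 3 (median -0.74). Histones had 7 down and 1 up of 10 (median -2.29, camera adjusted p = 0.00316, adjusted p = 0.42 with an estimated correlation), with 8 of 10 above both in that library (median 0.44). Markers of a-cells fell in 6 of 7 cases and rose in 0 (median -2.17, camera adjusted p = 3.04e-05, adjusted p = 0.091 with an estimated correlation), among them BAR1, a secreted protease, from 494 ± 21.3 to 40.8 ± 4.20 CPM. Haploid-specific genes fell in 8 of 11 cases and rose in 0 (median -1.0, camera adjusted p = 0.00916, adjusted p = 0.29 with an estimated correlation). HO (YDL227C), the mating-type switching endonuclease, had the lowest change of the named genes at -6.5 ± 0.37. Counts adjusted over the list alone were the same for all lists of falling transcripts given so far.

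Transcripts for growth on carbon sources other than glucose rose. All 20 measured genes of gluconeogenesis, the glyoxylate cycle and non-fermentable carbon use rose, with a median of 7.24 (camera adjusted p = 3.83e-25, and 0.048 with an estimated correlation). FBP1 (YLR377C), the gluconeogenic fructose-1,6-bisphosphatase, rose by 10.73 ± 1.37, from 1.34 ± 0.591 to 2176 ± 1935 CPM. MLS1 (YNL117W), malate synthase, rose by 10.80 ± 1.05 and JEN1 (YKL217W), the lactate transporter, by 9.40 ± 0.55. In the tricarboxylic acid cycle 18 of 19 genes rose and 0 fell (median 3.58, camera adjusted p = 4.68e-14, and 0.048 with an estimated correlation), including the succinate dehydrogenase gene SDH1 at 4.95 ± 0.36. Nuclear genes of oxidative phosphorylation rose in 33 of 34 cases, all 34 adjusted over the list alone (median 2.27, camera adjusted p = 1.06e-14, adjusted p = 0.29 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 43 of 69 cases and fell in 0 (median 0.84, camera adjusted p = 9.21e-06, adjusted p = 0.50 with an estimated correlation), the opposite direction to their cytosolic counterparts. Trehalose and glycogen genes rose in 19 of 20 cases and fell in 1 (median 3.24, camera adjusted p = 2.52e-09, adjusted p = 0.33 with an estimated correlation). The general stress list had 38 of 42 genes up, 40 adjusted over the list alone, and 0 down (median 3.29, camera adjusted p = 5.88e-11, adjusted p = 0.36 with an estimated correlation). It included XBP1, a stress-induced repressor, at 5.27 ± 0.25 and the small heat shock gene HSP12 at 7.19 ± 1.16. HSP12 RNA was at 270, 253 and 3330 CPM in -GLU replicates 1, 2 and 3, and its change ranged from 4.96 to 7.67 with 1 library left out. In -GLU RNA replicate 3, 34 of the 42 stress transcripts lay above both other replicates (median log2 difference 1.18) and 15 of the 20 gluconeogenesis transcripts below both (median -0.95), while 16 of 20 trehalose and glycogen transcripts (0.64) and 24 of 34 of oxidative phosphorylation (0.25) lay above both. Counts adjusted over the list alone were the same where 1 count is given.

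Glycolysis and fermentation genes split in RNA, with 12 down and 6 up of 21 (median -1.20, camera adjusted p = 0.297, also by the list alone 12 and 6). The risers included HXK1, a hexokinase gene repressed by glucose, at 7.34 ± 1.00 (5.98 to 7.84 with 1 library left out), the glucokinase gene GLK1 at 4.43 ± 0.58 and PYK2, a second pyruvate kinase, at 4.10 ± 0.48. PDC1 (YLR044C), the main pyruvate decarboxylase, fell by 3.90 ± 0.77 (log2 change -5.22 to -3.48 with 1 library left out). In -GLU RNA replicate 3, 20 of the 21 transcripts lay above both other replicates, by a median of 1.95, and without this library the list was called lower (median -2.66, adjusted p = 0.0342, range over its alternatives 0.0342 to 0.94). PGK1, phosphoglycerate kinase, changed by -1.55 ± 0.77 (adjusted p = 0.111), and by -2.72 without the same library (adjusted p = 0.00631, range over its alternatives 1.10e-04 to 0.73). Hexose transporters and sensors were called higher as a list (median 0.94, 7 up and 2 down of 16, camera adjusted p = 0.0452, adjusted p = 0.50 with an estimated correlation), with HXT5 at 8.93 ± 0.74 and the glucose-induced HXT1 at -2.25 ± 0.32. That call was lost without +GLU RNA replicate 1 (median 1.21, adjusted p = 0.0899) or 2 (0.77, 0.0571), with total counts (1.02, 0.0665) and with near-identical pairs summed (0.53, 0.0704), with a range over its alternatives of 0.00671 to 0.50. The protein kinase A list was higher (median 1.00, 13 up and 3 down of 23, camera adjusted p = 0.0225, adjusted p = 0.42 with an estimated correlation). TPK2, for a catalytic subunit, rose by 2.63 ± 0.35, and TPK3, for another, fell by 1.42 ± 0.24, while BCY1, the regulatory subunit, rose by 2.21 ± 0.28. Adjusted over the list alone, the counts of the hexose and kinase lists were the same.

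FLO11 (YIR019C), the flocculin of filamentous growth, rose by 2.12 ± 0.44 in RNA, from 1345 ± 141 to 5866 ± 1876 CPM (adjusted p = 0.00253). Its list of 39 filamentous and invasive growth genes was not called (12 up, 9 down, median -0.03, mean 0.10, camera adjusted p = 0.78). SUC2, the glucose-repressed invertase, rose by 5.37 ± 0.49, and GCN4, the activator of amino acid genes, changed by 0.18 ± 0.30 (adjusted p = 0.63). Further lists were not called in RNA. The proteasome had 2 genes up and 1 down of 34, 1 and 0 adjusted over the list alone (median -0.12, camera adjusted p = 0.859), and chaperones 12 up and 9 down of 30 (median 0.35, camera adjusted p = 0.812). The glucose repression and Snf1 list had 12 up and 6 down of 26, 12 and 7 adjusted over the list alone (median 0.10, camera adjusted p = 0.108). Cell wall genes had 5 up and 16 down of 36 (median -0.75, camera adjusted p = 0.115) and were called lower without -GLU RNA replicate 1 (median -0.81, adjusted p = 0.0467, range over their alternatives 0.0467 to 0.80). Alpha-cell markers had 1 up and 1 down of 3 (median 0.20, mean -0.04, camera adjusted p = 0.968), and meiosis genes 6 up and 7 down of 25, 6 and 6 adjusted over the list alone (median 0.10, mean -0.08, camera adjusted p = 0.968). The other counts were the same when adjusted over the list alone.

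In all, 3343 of 5519 genes tested changed in RNA (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 1678 up and 1665 down, and 2469 of them by at least 2-fold. The libraries of the states did not overlap for 3777 genes (68.4%), where chance gives 10%. The largest rise among the named genes was RGI2 (YIL057C), a gene of respiratory growth, at 11.53 ± 0.65 (0.519 ± 0.262 to 1246 ± 614 CPM). Poly(A) RNA of +GLU replicates 2 and 3 was selected on DynaBeads and that of the other 4 libraries on cellulose. With the cellulose libraries alone, and therefore 1 library with glucose, 1764 genes were called, 1706 of them among the 3343, and FLO11, HXK1, PCK1, HSP12, HSP26, PDC1, TDH1 and DPA10 lost their calls at log2 changes of 2.05, 6.97, 8.95, 7.64, 4.20, -3.32, 4.65 and 9.10. In that fit the lone +GLU library was assumed to vary like the -GLU libraries, and these losses do not bear on the selection material.

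**Figure D1:**
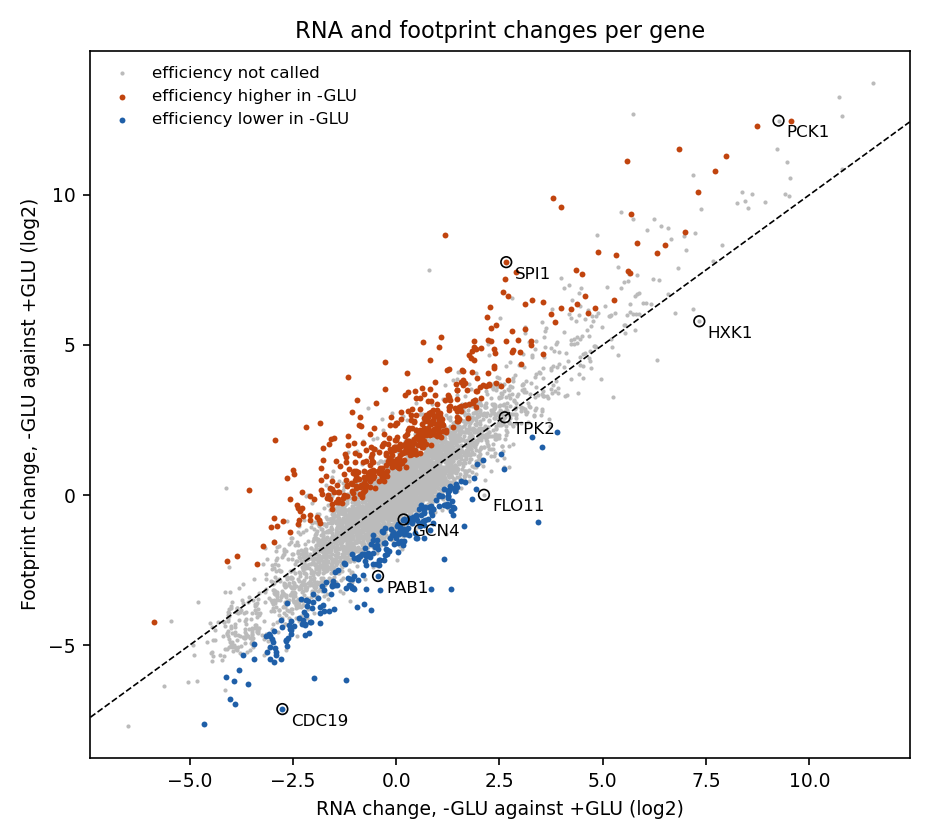
Log2 change without against with glucose for each of 5315 genes tested in both assays, in RNA (x axis) and in ribosome footprints (y axis), with genes called in translational efficiency coloured, labelled genes ringed and a dashed line of equal change. The changes correlated across genes (Pearson r = 0.90), with a wider spread in footprints (SD 2.25) than in RNA (1.77).

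The second comparison asked which genes held a larger or smaller share of the footprints. Counts were scaled between libraries, so rises and falls are relative to other genes. A change of all genes together would not be seen in RNA, footprints or efficiency. Footprints on the translation apparatus fell. All 136 cytosolic ribosomal protein genes fell, by a median of -4.57 (camera adjusted p = 1.24e-56, and 0.033 with an estimated correlation), RPL31B from 887 ± 51.7 to 22.1 ± 2.28 CPM. All 66 biogenesis genes fell (median -3.23, camera adjusted p = 1.10e-24, adjusted p = 0.23 with an estimated correlation), and 52 of 66 lay below both other replicates in -GLU footprint replicate 3 (median -0.79). Initiation factors fell in 25 of 26 cases (median -1.94, camera adjusted p = 4.37e-07, adjusted p = 0.23 with an estimated correlation) and elongation and termination factors in 9 of 12 (median -2.62, camera adjusted p = 3.84e-04, adjusted p = 0.23 with an estimated correlation), with 0 higher. PAB1 (YER165W), the poly(A)-binding protein, fell by 2.70 ± 0.43 and YEF3, elongation factor 3, by 6.29 ± 0.72. Glycolysis and fermentation had 15 genes down and 4 up of 21 (median -3.08, camera adjusted p = 0.00362, adjusted p = 0.57 with an estimated correlation). PDC1 footprints fell from 26068 ± 2895 to 209 ± 83.3 CPM and those of CDC19, pyruvate kinase, by 7.13 ± 0.71, while GLK1 rose by 4.05 ± 0.38. In -GLU footprint replicate 3, 18 of 20 genes of this list lay above both other replicates, by a median of 1.84. Amino acid biosynthesis had 50 of 57 genes down and 0 up (median -2.21, camera adjusted p = 2.75e-11, adjusted p = 0.30 with an estimated correlation), HOM3, aspartate kinase, falling by 4.47 ± 0.27. Ergosterol biosynthesis had 22 of 23 down and 0 up (median -1.96, camera adjusted p = 2.27e-04, adjusted p = 0.42 with an estimated correlation), and 17 of 23 lay below both other replicates in -GLU footprint replicate 3 (median -1.32). The cell wall list had 5 up and 17 down of 33, 5 and 18 adjusted over the list alone (median -1.38, camera adjusted p = 0.0184, adjusted p = 0.68 with an estimated correlation), and 27 of 32 of its genes lay below both other replicates in -GLU footprint replicate 3. Markers of a-cells fell in 5 of 7 cases and rose in 0 (median -3.34, camera adjusted p = 0.00125, adjusted p = 0.21 with an estimated correlation). Haploid-specific genes had 8 down and 1 up of 10, 8 and 2 adjusted over the list alone (median -0.87, camera adjusted p = 0.0125, adjusted p = 0.23 with an estimated correlation). The counts of the other lists were the same when adjusted over the list alone.

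Footprints on genes of respiration and stress rose. All 20 gluconeogenesis and non-fermentable carbon genes rose (median 9.34, camera adjusted p = 8.72e-16, adjusted p = 0.23 with an estimated correlation), including ICL1 (YER065C), isocitrate lyase, at 12.28 ± 1.23 and PCK1 (YKR097W), phosphoenolpyruvate carboxykinase, at 12.47 ± 2.05. In -GLU footprint replicate 3, 18 of the 20 lay below both other replicates, by a median of -0.88. RGI2 had 3 footprint counts in the +GLU libraries together and 38055 in the -GLU libraries, a ratio of 19213 after scaling for depth (95% exact interval 6574 to 93170). SPG1, a stationary-phase gene, had 0 and 1664, at least 840-fold higher against a floor of 3 counts over the group. In the tricarboxylic acid cycle 17 of 19 genes rose and 1 fell (median 3.32, camera adjusted p = 4.45e-06, adjusted p = 0.30 with an estimated correlation). Oxidative phosphorylation rose in 33 of 34 genes, all 34 adjusted over the list alone (median 2.78, camera adjusted p = 2.75e-11, and 0.040 with an estimated correlation). Mitochondrial ribosomal proteins rose in 68 of 69 cases, all 69 adjusted over the list alone (median 1.92, camera adjusted p = 9.28e-13, adjusted p = 0.23 with an estimated correlation). All 41 stress genes rose (median 5.79, camera adjusted p = 1.22e-12, adjusted p = 0.23 with an estimated correlation), HSP12 by 10.66 ± 1.25 (9.13 to 11.15 with 1 library left out), and in -GLU footprint replicate 3, 28 of 42 lay above both other replicates, by a median of 1.38. The median change of the stress list ranged from 4.44 to 6.31 over its alternatives. Trehalose and glycogen genes rose in 17 of 20 cases and fell in 1 (median 2.83, camera adjusted p = 1.99e-06, adjusted p = 0.30 with an estimated correlation). In the same library 17 of 20 of these lay above both others (median 0.87), and 15 of 19 genes of the tricarboxylic acid cycle (-0.75) and 41 of 69 mitochondrial ribosomal protein genes (-0.30) below both. Other counts did not change when adjusted over the list alone.

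FLO11 footprints were 3096 ± 379 CPM with glucose and 3113 ± 2108 without (log2 change 0.01 ± 0.63, adjusted p = 0.992), against the higher FLO11 RNA, and 681 CPM in -GLU replicate 3. TPK2 rose by 2.59 ± 0.34 and TPK3 fell by 1.30 ± 0.28. SUC2 rose by 4.67 ± 0.43 and HXT1 fell by 3.19 ± 0.35. HXT3, a low-affinity glucose transporter, fell by 1.84 ± 0.60 (adjusted p = 0.0287), a call lost without +GLU footprint replicate 1 (0.0526) or 2 (0.0524) or -GLU replicate 1 (0.0782), with a range over its alternatives of 0.00139 to 0.0782. GCN4 changed by -0.81 ± 0.43 (adjusted p = 0.136), and by -1.36 without -GLU footprint replicate 3 (0.0031, range over its alternatives 0.0031 to 0.53).

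Other lists were not called in footprints. Hexose transporters had 7 genes up and 3 down of 11 (median 2.86, camera adjusted p = 0.184), the proteasome 3 up and 0 down of 34, 1 and 0 adjusted over the list alone (0.13, 0.911), and chaperones 9 up and 10 down of 30 (median 0.31, mean -0.04, 0.553). Filamentous growth genes had 12 up and 13 down of 39 (0.01, 0.989), the protein kinase A list 12 up and 3 down of 23 (0.74, 0.108) and the Snf1 list 10 up and 5 down of 26 (0.26, 0.165). Histones had 1 up and 3 down of 10, 1 and 2 adjusted over the list alone (-0.66, 0.287), alpha-cell markers 1 up and 1 down of 3, 2 and 1 adjusted over the list alone (0.61, 0.801), and meiosis genes 8 up and 0 down of 18 (1.54, 0.0826). The remaining counts were the same adjusted over the list alone. Without -GLU footprint replicate 3 the histones (-1.14, adjusted p = 0.0095) and the hexose transporters (2.62, 0.0469) were called, and without +GLU footprint replicate 1 or 3 the meiosis list (1.44, 0.0286 and 1.74, 0.0151).

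Of 5319 genes tested, 3446 changed in footprints, 1798 up and 1648 down (edgeR quasi-likelihood test), 2736 by at least 2-fold, and 3841 (72.2%, chance 10%) had libraries that did not overlap between the states. Scaling by total counts, which moved the median change of all genes from 0.10 to 0.55, gave 2416 up and 1200 down, and the deposited RPKM values 2322 up and 1232 down. Among 5315 genes tested in both assays, 1307 rose in both (554 for independent lists) and 1262 fell in both (503), while 14 rose in RNA and fell in footprints and 34 did the reverse. Across these genes, which are not independent replicates, footprint and RNA changes had a Spearman rho of 0.86 and the slope of footprint on RNA change was 1.15.

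**Figure D2:**
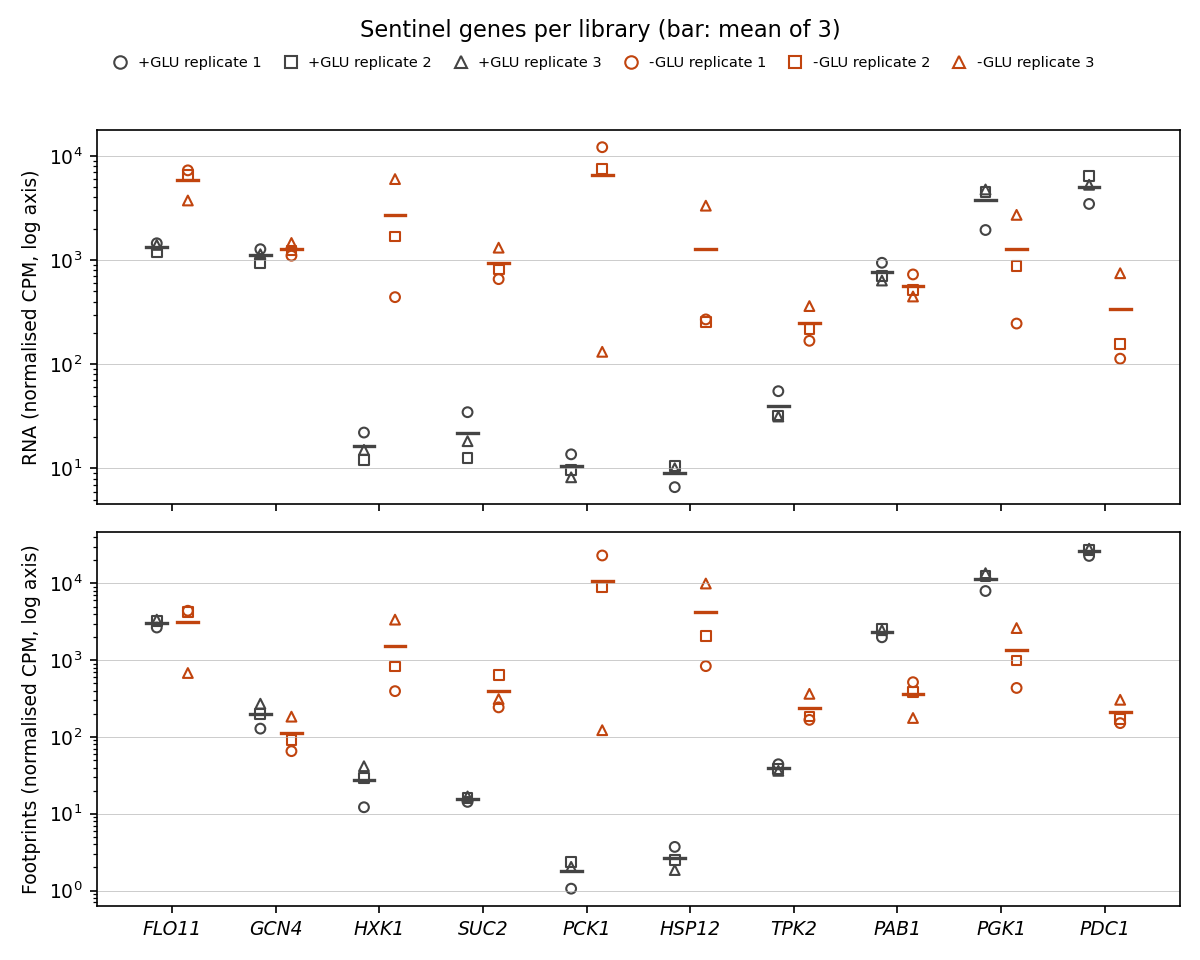
Normalised CPM (log axis) of 10 genes chosen in advance, in RNA (upper panel) and footprint libraries (lower panel), with 3 libraries with and 3 without glucose shown as points by replicate and bars at the mean of 3. FLO11 RNA lay higher in all 3 libraries without glucose whereas its footprints overlapped between the states, and PCK1 lay far lower in -GLU replicate 3 than in the other -GLU replicates.

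The main comparison of the series concerned translational efficiency, the footprint level of a gene relative to its RNA level, tested as the footprint change minus the RNA change. At the preset correlation, efficiency moved in opposite directions for the mitochondrial and cytosolic translation apparatus. No efficiency list was called with an estimated correlation. All efficiency changes rest on footprints taken with cycloheximide. Mitochondrial ribosomal protein genes rose in 30 of 69 cases, 45 adjusted over the list alone, and fell in 0 (median log2 change 1.06, camera adjusted p = 2.80e-13, adjusted p = 0.41 with an estimated correlation). MRPL32 (YCR003W) rose by 2.07 ± 0.29, its footprints going from 65.1 ± 5.97 to 220 ± 38.0 CPM while its RNA went from 57.4 ± 7.13 to 46.2 ± 8.52. Cytosolic ribosomal protein genes fell in 17 of 138 cases, also 17 adjusted over the list alone, and rose in 0 (median -0.83, camera adjusted p = 4.43e-13, adjusted p = 0.58 with an estimated correlation), RPL6B by 2.55 ± 0.40. Biogenesis genes fell in 5 of 66 cases, 4 adjusted over the list alone (median -0.89, camera adjusted p = 1.63e-07, adjusted p = 0.58 with an estimated correlation). Over the alternatives the median ranged from -1.28 to -0.65 for cytosolic ribosomal proteins and from -1.40 to -0.69 for biogenesis. The deviation of -GLU replicate 3 differed between RNA and footprints, with medians of -0.71 and -0.12 for ribosomal proteins and -1.52 and -0.79 for biogenesis. Initiation factors fell in 5 of 26, 6 adjusted over the list alone (median -0.75, camera adjusted p = 9.01e-05, adjusted p = 0.41 with an estimated correlation), RPG1, a subunit of eIF3, by 1.98 ± 0.37. Elongation and termination factors fell in 3 of 12, 4 adjusted over the list alone (median -0.90, camera adjusted p = 4.50e-04, adjusted p = 0.41 with an estimated correlation). PAB1 fell by 2.20 ± 0.52 (adjusted p = 0.0186), with RNA of 600 ± 127 and 445 ± 118 CPM and footprints of 2903 ± 412 and 467 ± 221. The PAB1 call was lost without +GLU footprint replicate 2 (0.056) or +GLU RNA replicate 3 (0.0565) or with the poly(A) covariate (0.109), with a range over its alternatives of 6.13e-05 to 0.109. Amino acid biosynthesis genes fell in 15 of 58 cases, 16 adjusted over the list alone, and rose in 0 (median -0.90, camera adjusted p = 7.77e-12, adjusted p = 0.41 with an estimated correlation), THR4, threonine synthase, by 1.82 ± 0.35.

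Glycolysis and fermentation genes fell in efficiency in 5 of 21 cases, also 5 adjusted over the list alone, and rose in 0 (median -1.54, camera adjusted p = 2.45e-06, adjusted p = 0.58 with an estimated correlation). Their median ranged from -2.22 to -0.75 over the alternatives. PDC5 (YLR134W), a minor pyruvate decarboxylase, was the lowest named gene at -4.90 ± 0.64 (adjusted p = 0.00144), and CDC19 fell by 4.31 ± 0.93, a call lost with the poly(A) covariate (0.0717). Gluconeogenesis and non-fermentable carbon genes rose in 5 of 20 cases, also 5 adjusted over the list alone, and fell in 0 (median 1.48, camera adjusted p = 0.00663, adjusted p = 0.58 with an estimated correlation). They included ACS1, acetyl-CoA synthetase, at 3.13 ± 0.59 and the glycerol kinase gene GUT1 at 2.02 ± 0.35. The stress list rose in 9 of 42 genes, also 9 adjusted over the list alone, and fell in 0 (median 1.64, camera adjusted p = 3.56e-05, adjusted p = 0.58 with an estimated correlation), with OM45, a mitochondrial outer membrane protein, at 2.73 ± 0.52. Cell wall genes fell in 4 and rose in 2 of 36 cases, 8 and 2 adjusted over the list alone (median -0.58, camera adjusted p = 8.21e-04, adjusted p = 0.58 with an estimated correlation). TIR1 (YER011W), a cell wall mannoprotein, fell by 4.07 ± 0.42 and the flocculin FLO10 by 4.40 ± 0.70. Meiosis genes rose in 5 and fell in 1 of 25 cases, 6 and 1 adjusted over the list alone (median 1.38, camera adjusted p = 0.00236, adjusted p = 0.41 with an estimated correlation), SPR28, a septin of sporulation, by 2.89 ± 0.60. In -GLU replicate 3, glycolysis genes lay above both other replicates in 20 of 21 cases in RNA and 18 of 20 in footprints, and cell wall genes below both in 30 of 37 and 27 of 32.

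Other list calls were lost without single libraries and under other settings. Chaperones had 2 genes down and 0 up of 30, 0 down adjusted over the list alone (median -0.49, camera adjusted p = 0.022, adjusted p = 0.58 with an estimated correlation). Their call was lost without -GLU footprint replicate 3 (0.068), +GLU RNA replicate 1 (0.192), -GLU RNA replicate 2 (0.086) or -GLU RNA replicate 3 (0.102), and without both -GLU replicate 3 libraries (0.0935). Ergosterol genes had 1 down of 23, 0 adjusted over the list alone (median -0.56, camera adjusted p = 0.0103, adjusted p = 0.58 with an estimated correlation), lost without -GLU footprint replicate 3 (0.128) or +GLU RNA replicate 1 (0.0761). The a-cell markers had 2 down of 7, 3 adjusted over the list alone (median -0.57, camera adjusted p = 0.0457, adjusted p = 0.41 with an estimated correlation), lost without any 1 of 7 libraries, namely +GLU footprint replicate 3 (0.0571), -GLU footprint replicate 1 (0.0952) or 2 (0.0573), +GLU RNA replicate 1 (0.0847) or 2 (0.0719), and -GLU RNA replicate 1 (0.0612) or 3 (0.128). The a-cell call was also lost with RLE factors (0.0501), with the replicate number as a block (0.0647) and without both -GLU replicate 3 libraries (0.0512).

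The proteasome was not called in efficiency (0 up and 0 down of 34, median 0.21, camera adjusted p = 0.678), nor were hexose transporters (1 up of 15, 0 adjusted over the list alone, 0.76, 0.959) or trehalose and glycogen genes (1 down of 20, 0.29, 0.959). Filamentous growth genes had 3 up and 2 down of 39 (-0.09, 0.249), the protein kinase A list 1 up and 1 down of 23 (median -0.05, mean 0.06, 0.589) and the Snf1 list 3 up of 26 (0.17, 0.959). Alpha-cell markers had 1 up of 3 (0.46, 0.419) and haploid-specific genes 1 down of 10 (median 0.13, mean -0.16, 0.407). The tricarboxylic acid cycle, with 2 down of 19 (-0.21, 0.0501), was called lower without +GLU footprint replicate 1 (0.0274), -GLU footprint replicate 1 (0.019) or 2 (0.0263), +GLU RNA replicate 3 (0.0413) or -GLU RNA replicate 2 (0.0384), and with total counts (0.0292). Oxidative phosphorylation, with 4 up of 34, 1 adjusted over the list alone (0.48, 0.0953), was called higher without -GLU RNA replicate 3 (0.0122) or both -GLU replicate 3 libraries (0.68, 0.00535), and histones, with 3 up of 10 (1.14, 0.12), without -GLU footprint replicate 1 (0.0297) or -GLU RNA replicate 3 (0.0314). Single counts were the same when adjusted over the list alone.

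Of the 8 named genes with the highest rise, all but SAD1 had under 3 CPM of footprints with glucose, with RNA between 3.41 and 78.7 CPM. YIG1 (YPL201C) rose by 5.66 ± 0.58 (adjusted p = 3.70e-04), with footprints of 0.331 ± 0.324 and 777 ± 145 CPM and RNA of 7.47 ± 1.68 and 355 ± 31.9, and SPI1, a cell wall protein of stationary phase, by 5.14 ± 0.93. For 4 genes the fitted change rested on 2 or fewer footprint counts with glucose, and their footprint ratio is given instead. FMP33 had 2 and 1549 counts (ratio 1173, interval 324 to 9695) and YIR016W 1 and 420 (ratio 636, interval 114 to 25186). YLR342W-A had 2 and 11 (ratio 8.33, interval 1.82 to 77.3) and YOL029C 0 and 13, at least 6.56-fold higher. The efficiency call of YLR342W-A was lost without any 1 of 8 libraries and its sign turned without 1 more (range -0.73 to 8.51). That of RTN2, a reticulon, at 5.74 ± 1.61 was lost without any 1 of 9 libraries (adjusted p up to 0.10). SAD1, a splicing factor, rose by 5.14 ± 1.05, with footprints of 317, 2835 and 274 CPM in the 3 -GLU libraries and 72.6 ± 35.0 with glucose. Lower named genes included PAD1 at -3.96 ± 0.57, UTH1 at -3.17 ± 0.45 and DSF1 at -4.28 ± 0.82, whose call was lost with the poly(A) covariate (0.0582). ATF1, an alcohol acetyltransferase, at -3.27 ± 0.81, lost its call without +GLU footprint replicate 2 (0.0634) or +GLU RNA replicate 3 (0.0586) or with the poly(A) covariate (0.119), and PDC1, at -3.0 ± 0.91 (adjusted p = 0.0464), without any 1 of 9 libraries (up to 0.10).

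FLO11 efficiency changed by -2.07 ± 0.77 and did not pass the test (adjusted p = 0.0918). Without both -GLU replicate 3 libraries it was -1.84 (0.00457), without -GLU footprint replicate 3 alone -1.60 (0.0365) and without -GLU RNA replicate 3 alone -2.52 (0.0397). FLO11 was also called with DESeq2 (-2.19, 0.014), with the footprint and RNA library of 1 number in a block by culture (-2.40, 0.0069) and without the 3 libraries counted over a longer region (-2.11, 5.71e-04). It was not called under the other 21 of 27 alternatives (adjusted p up to 0.264). The block by culture, the fit without the longer-region libraries and that without both -GLU replicate 3 libraries were chosen after the data were seen. The kinase subunits TPK2 and TPK3 changed by 0.02 ± 0.51 and 0.17 ± 0.38 (adjusted p = 0.98 and 0.787). PCK1 changed by 3.27 ± 2.01 (0.286) and HSP12 by 3.56 ± 1.49 (0.128). Both were called without both -GLU replicate 3 libraries (3.29, 0.00525 and 4.24, 4.39e-04), with the block by culture (2.91, 0.00434 and 3.88, 9.23e-04) and without the longer-region libraries (2.75, 0.0101 and 4.31, 4.53e-04), and HSP12 without -GLU RNA replicate 3 alone (5.69, 0.00945). Their adjusted p over the alternatives ranged from 0.00434 to 0.58 and from 4.39e-04 to 0.328. GCN4 changed by -0.93 ± 0.53 (0.25) and was called without -GLU footprint replicate 3 (-1.48, 0.034), without both -GLU replicate 3 libraries (-1.37, 0.0271) and without the longer-region libraries (-1.69, 0.00817), with a range of 0.00817 to 0.52. HXK1 (-1.48 ± 1.23), SUC2 (-0.65 ± 0.60), HXT1 (-0.89 ± 0.46), HXT3 (-0.05 ± 0.64), HSP26 (1.55 ± 1.30) and PGK1 (-1.46 ± 1.10) did not pass the test with all 12 libraries, with adjusted p from 0.21 to 0.967, and PGK1 was called with the block by culture (-1.30, 0.0433).

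In total 756 of 5509 genes changed in efficiency, 509 up and 247 down (67.3% up, edgeR quasi-likelihood test), and 703 by at least 2-fold. The share of rising genes moved with the scaling, with 379 up and 326 down under RLE factors and 769 and 137 under total counts. DESeq2, which differs in scaling, dispersion and test, gave 559 and 525. It was under 50% without any 1 of 5 RNA libraries, at 41.0% and 46.3% without +GLU RNA replicates 1 and 2 and 44.0%, 44.1% and 41.1% without -GLU RNA replicates 1, 2 and 3. It was 74.2% without +GLU RNA replicate 3 and 66.4% to 74.1% without any 1 footprint library. The count was 273 without +GLU footprint replicate 2, 374 without 3, 493 without 1, 357 without +GLU RNA replicate 3, 445 without 2 and 320 without -GLU RNA replicate 2. Without both -GLU replicate 3 libraries it was 1378, holding 732 of the 756. Footprint and RNA libraries of 1 number deviated together within -GLU (correlation 0.38 to 0.60), which the model left out. Replicate 3 stood apart in both assays, and footprint replicate 1 also correlated with RNA replicate 2 at 0.37. The correlations therefore do not show what replicates 1 and 2 share by number. With a block by culture, chosen after the data were seen, 1431 genes were called, 821 up and 610 down, holding 748 of the 756. The name is used for short, since the labels do not say that libraries of 1 number shared a culture. Without the 3 libraries counted over the longer region, also chosen then, 2161 were called, 38.4% of them up, and 701 of the 756 were among them. The count was 322 with the poly(A) material as a covariate and 393 with the replicate number as a block. Of 489 genes that rose in efficiency and were tested in both assays, 386 rose and 18 fell in footprints, and RNA rose for 189, fell for 129 and was not called for 171. Of 246 that fell, 195 fell and 7 rose in footprints, and RNA rose for 65, fell for 110 and was not called for 71.

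**Figure D3:**
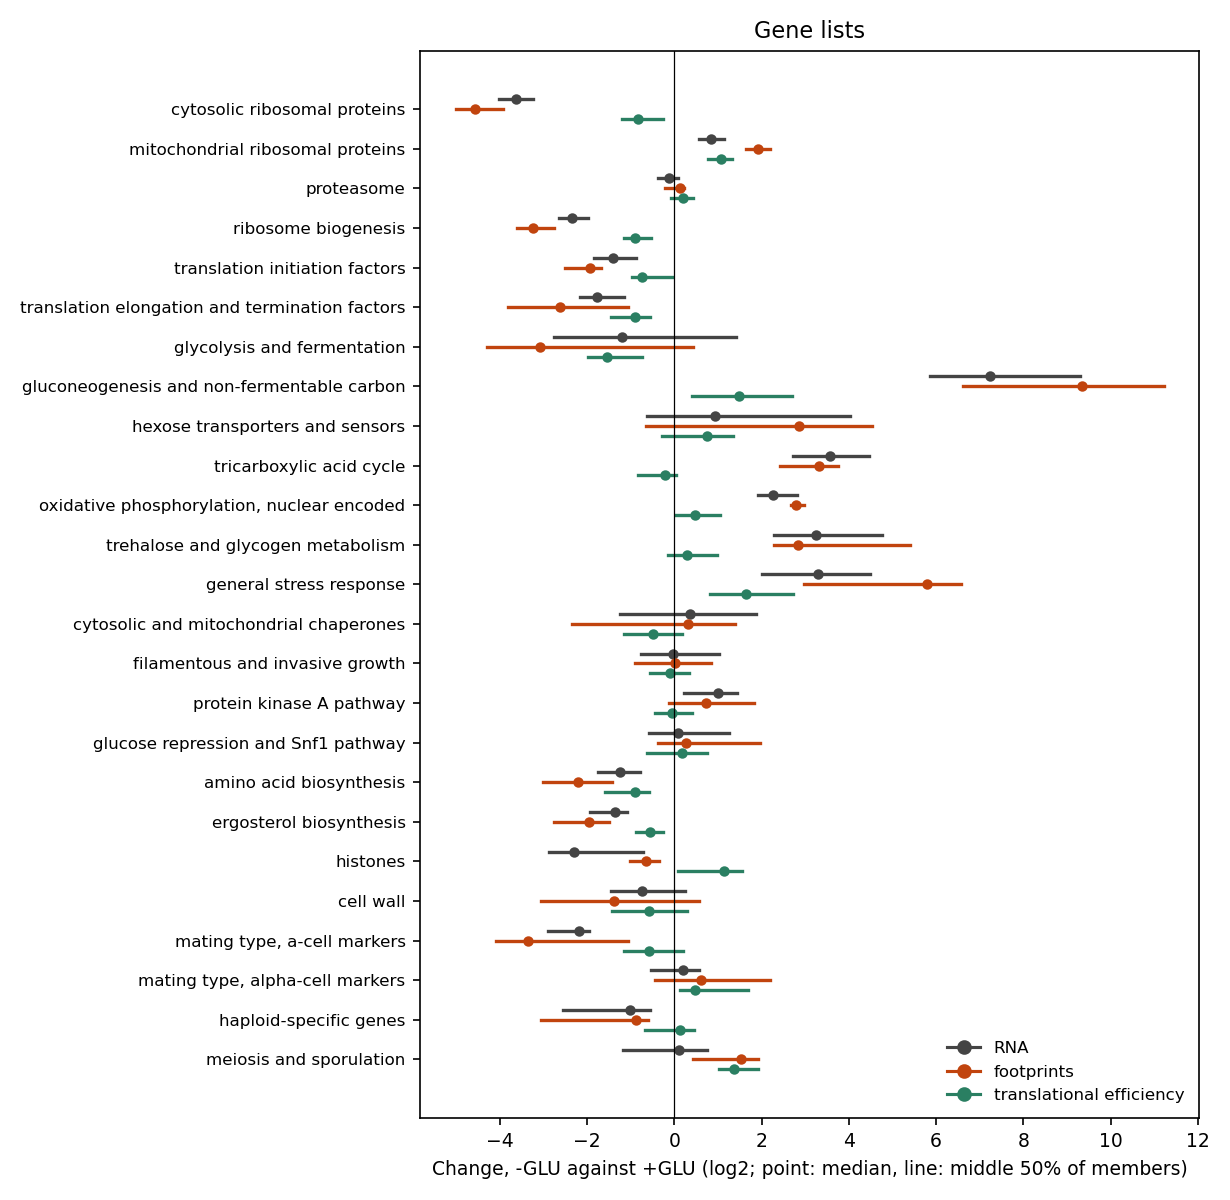
Median log2 change without against with glucose of the 25 gene lists in RNA, footprints and translational efficiency, with lines over the middle 50% of members. Gluconeogenesis lay highest in RNA (7.24) and footprints (9.34) and cytosolic ribosomal proteins lowest (-3.63 and -4.57).

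The libraries titled as lacking cycloheximide asked whether the footprint changes were also seen without the drug. By their titles, the fast-harvest libraries differed from the replicated ones in harvest as well as in the drug. A difference from the replicated changes therefore cannot be assigned to the drug alone. There was 1 library per state, so these ratios have no replicate check and no test, and their intervals cover counting error only. In the fast-harvest libraries, ribosomal protein footprints were lower without glucose for all 136 genes (median log2 ratio -3.60, below all of 10000 random lists of like expression). All 66 biogenesis genes (median -2.97, percentile 0) and all 26 initiation factors (-1.73, percentile 0.11) were lower. Elongation factors (-2.00, 2.39), glycolysis (-2.53, 0.205), amino acid biosynthesis (-1.21, 0.01) and a-cell markers (-3.47, 0) had low medians too. High medians were those of gluconeogenesis (9.59), the tricarboxylic acid cycle (3.78), oxidative phosphorylation (3.10), trehalose and glycogen (2.97), stress (4.20) and mitochondrial ribosomal proteins (1.98), each at percentile 100. Hexose transporters (3.08, 99.9) and protein kinase A (1.14, 99.6) were also high. The medians of the other lists were 0.26 for the proteasome (percentile 88.0), 0.11 for chaperones (83.7), 0.34 for filamentous growth (57.7), 0.36 for the Snf1 pathway (59.9) and 2.28 for meiosis (95.4). Below 0 were ergosterol (-0.79, 7.93), histones (-0.49, 33.5), the cell wall (-0.45, 12.8), alpha-cell markers (-1.31, 1.53) and haploid-specific genes (-0.31, 8.18). Ribosomal protein and amino acid medians lay near those of RNA (-3.63 and -1.25), against -4.57 and -2.21 in footprints with the drug. Biogenesis, initiation and elongation factors, glycolysis and mitochondrial ribosomal proteins stayed beyond their RNA medians (-2.35, -1.40, -1.76, -1.20 and 0.84). Ergosterol and the cell wall fell short of theirs (-1.36 and -0.75). These ratios were scaled by total counts (median of all genes 0.31). No RNA library goes with them, so efficiency was not tested.

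The highest ratios were those of PCK1, with 230151 counts without glucose against 41 with it (log2 14.24, exact interval 13.85 to 14.77), MLS1 (13.72), ADY2 (13.01), ICL1 (12.93), JEN1 (12.81) and the catalase gene CTA1 (12.43). The lowest were RPL9A (-5.33), IMD4 (-5.26), NSR1 (-5.20), ATF2 (-5.13), SST2 (-5.02) and CDC19 (-4.84). FLO11 had a ratio of 0.67 (0.64 to 0.70), TPK2 of 2.72, TPK3 of -0.63, GCN4 of -0.97, PAB1 of -2.55, SUC2 of 3.43, HSP12 of 11.95 and HSP26 of 5.35. TIR1 had a ratio of -1.06, against a replicated change of -6.10 with cycloheximide. Across 5169 genes the ratio correlated with the replicated footprint change at a Spearman rho of 0.936 and a Pearson r of 0.953, and 3251 of 3343 genes called there (97.2%) had the same sign. The ratio reached 2-fold upward in 1624 and downward in 1003 of 5180 genes.

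**Figure D4:**
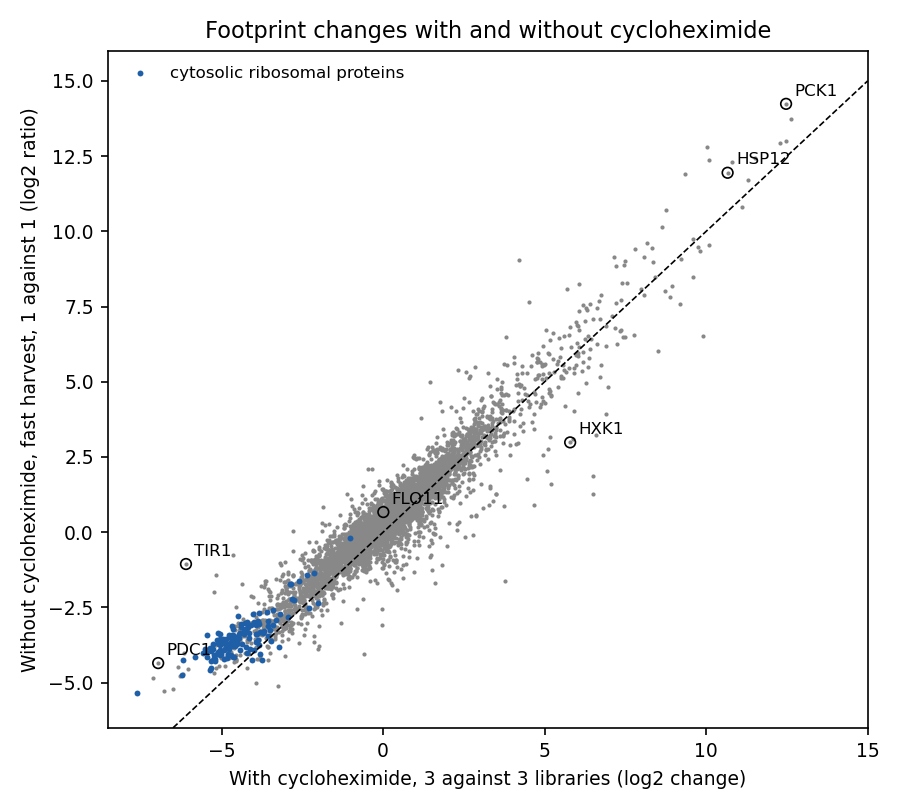
Log2 footprint change without against with glucose in the replicated cycloheximide libraries (x axis) against the log2 ratio of the single fast-harvest libraries without the drug (y axis), 1 point per gene, with cytosolic ribosomal proteins in blue, labelled genes ringed and a dashed line of equal change. The changes correlated at a Spearman rho of 0.936 across 5169 genes.

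A further single library without glucose, titled without the word fast, was set against the fast-harvest one. It held lower ribosomal protein footprints (124 of 125 genes lower, median log2 ratio -1.79, percentile 0). Medians were also lower for the cell wall (-0.96, 0), elongation factors (-1.01, 0), ergosterol (-0.57, 0), mitochondrial ribosomal proteins (-0.24, 0), amino acid biosynthesis (-0.14, 0.415), glycolysis (-0.41, 0.69) and histones (-0.54, 0.93). They were higher for haploid-specific genes (1.47, 100), a-cell markers (0.96, 99.1), filamentous growth (0.60, 99.98), hexose transporters (0.92, 99.9) and protein kinase A (0.52, 99.0). FLO11 was at 6535 CPM against 1222 (log2 2.42, interval 2.38 to 2.46), HSP26 at 1790 against 217 (3.04) and GCN4 at a log2 ratio of 1.01, whereas PDC1 was lower (-2.70). Highest were NGL3 (4.55), CNA1 (4.30), RAD16 (3.78), CIS1 (3.59), SSA4 (3.47) and HSP30 (3.32), and lowest FRE7 (-4.63), FDH1 (-3.85), RPP2B (-3.61), PMP1 (-3.40), RPS20 (-3.32) and VMA3 (-3.26). The remaining lists had medians between -0.33 (gluconeogenesis, percentile 2.61) and 0.70 (meiosis, 93.3). Of 4881 genes, 391 were at least 2-fold higher and 496 at least 2-fold lower in this library. Set against the fast-harvest +GLU library in place of its fast-harvest counterpart, it gave a Spearman rho of 0.894 with the replicated footprint change, and FLO11 a log2 ratio of 3.09.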

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

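The comparison that singled out this gene was planned, and no test was chosen after the result was seen. The only result that met the rules for a closer look was HMS2, a transcription factor gene of filamentous growth. Its footprints without cycloheximide had a log2 ratio of -0.45 without against with glucose (1.63 and 2.26 CPM, from 14 and 69 counts, exact interval -1.41 to 0.38), whereas its replicated footprints with cycloheximide changed by 1.96 and all 3 lay higher without glucose. The difference between these changes was not tested, and the interval of the single-library ratio includes 0. The replicated +GLU footprint libraries held 9 HMS2 counts together (0.45 CPM), so the replicated change and the efficiency call rest on few counts. Its efficiency call (3.21 ± 0.71, adjusted p = 0.0136) was lost without +GLU footprint replicate 2 (0.0534). Groups of 3 libraries were not tested for single libraries far from the others.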

How the results depend on the processing

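Results that left out both -GLU replicate 3 libraries or the 3 libraries counted over the longer region, that took the footprint and RNA library of 1 number as a block by culture, that kept only genes with at least 10 counts in all 12 libraries, or that ran the lists under RLE factors or TMM within each assay, were chosen after the data were seen. The other alternatives were planned. Of 65 counts of calls under alternatives, 53 lay within 1.5 times the count reported and 12 did not. Of 962 list results 847 kept their direction and side of the threshold, 64 lost a call, 16 gained one and 35 turned direction, and for named genes these were 3386, 174, 28 and 37. For each changed or reversed result the cause was not tested.

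RNA calls ranged from 2772 to 3378 with 1 library left out and were 1764 with cellulose-selected libraries only. With the poly(A) material as a covariate, RNA calls were 2518, of which 2379 were among the 3343. That fit had 1 +GLU library selected on cellulose. It was also the only +GLU RNA library counted over the longer region and the deepest of them, so these cannot be told apart. Footprint calls ranged from 2884 to 3908. Efficiency calls ranged from 273 to 1034 with 1 library left out, and were 493, 273 and 374 without +GLU footprint replicates 1, 2 and 3, 445 and 357 without +GLU RNA replicates 2 and 3, and 320 without -GLU RNA replicate 2. They were 322 with the poly(A) material as a covariate, 1378 without both -GLU replicate 3 libraries, 1431 with a block by culture and 2161 without the libraries counted over the longer region. With the replicate block, efficiency calls were 393, of which 367 were among the 756, RNA calls 3134 and footprint calls 3281. Same-numbered RNA libraries of the states deviated together with a correlation of -0.13 to -0.052, and footprint libraries with 0.061 to 0.092, where 2 of 3 correlated best with their own number. The RNA libraries thus showed no sign of pairs across the states, and for footprints the correlations were too weak to decide. Footprint and RNA libraries of 1 number correlated at 0.38 to 0.60 within -GLU (3 of 3 best with their own) and at 0.070 to 0.13 within +GLU (3 of 3). Within -GLU, footprint replicate 1 and RNA replicate 2 correlated at 0.37, so the range is not particular to libraries of 1 number. The median log2 change of all genes was 0.01 in RNA, 0.10 in footprints and 0.13 in efficiency with TMM, 0.15, 0.55 and 0.36 with total counts, and 0.00, 0.07 and 0.02 with RLE factors. The rising share of footprint calls was 52.2% with TMM, 66.8% with total counts, and 65.3% with RPKM at pseudocounts of 1 and 0.1. That of efficiency calls was 67.3% with TMM, 53.8% with RLE factors, 51.6% with DESeq2, 84.9% with total counts, 46.3% with at least 10 counts in all 12 libraries, 38.4% without the longer-region libraries, 60.4% with TMM within each assay, and 82.1% and 83.6% with RPKM and pseudocounts of 1 and 0.1.

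Of the calls reported only that of YLR342W-A turned direction. The other reversals, by sign for genes and by the direction of camera for lists, had no call on either side. With total counts the medians were 0.23 for meiosis in RNA, 0.42 for filamentous growth in footprints, and 0.97, 0.66 and 0.42 for hexose transporters, trehalose and the Snf1 list in efficiency, and HXT3 efficiency was 0.18. With the replicate block, alpha-cell markers in RNA were at 0.30, hexose transporters and the Snf1 list in efficiency at 0.14 and 0.17, FLO11 footprints at -0.33 and TPK2 efficiency at -0.050. FLO11 footprints were -0.037 with DESeq2 and with RLE factors, -0.0047 with no filter and -0.50 with limma-voom, and GCN4 RNA was -0.0069 with the poly(A) covariate. TPK2 efficiency was -0.094 with DESeq2, -0.089 with RLE factors, -0.060 with TMM within each assay, -0.044 without both -GLU replicate 3 libraries, -0.052 with the block by culture, -0.10 with at least 10 counts and -0.61 without the longer-region libraries. HXT3 efficiency was 0.47 without both -GLU replicate 3 libraries, and 0.27 without the longer-region libraries. Without cycloheximide, 80 of 98 list medians lay within their intervals, 17 moved, 8 of them with median-ratio scaling and 9 with the other -GLU library, and 1 turned sign. The proteasome median was -0.065 with median-ratio scaling, and the correlation with replicated changes was 0.894 with the other -GLU library.

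With 1 library left out, RNA medians ranged from -0.27 to 0.052 for the proteasome, 0.16 to 0.53 for chaperones, 0.020 to 0.69 for alpha-cell markers and -0.13 to 0.19 for meiosis. Footprints of FLO11 ranged from -0.33 to 0.48, the proteasome from -0.029 to 0.21 and filamentous growth from -0.17 to 0.35. Efficiency ranged from -0.73 to 8.51 for YLR342W-A, -0.79 to 0.40 for HXT3, -0.25 to 2.84 for HSP26, -0.51 to 0.23 for TPK2 and -0.21 to 0.42 for TPK3. Its list medians ranged from -0.18 to 0.32 for the proteasome, -0.25 to 0.82 for hexose transporters, -0.22 to 0.56 for trehalose and -0.14 to 0.33 for the Snf1 list.

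Each comparison was refitted with edgeR over the 10 splits of its libraries into equal groups, a test chosen after the result was seen. In each, 1 of 10 splits, the real one, gave as many calls (3343, 3446 and 756), and the highest other gave 0, with at most 155, 80 and 55 genes under 0.05 before adjustment. With 10 splits the share cannot go under 0.1. Every other split put libraries of both glucose states in each group, which widens the spread within groups. Their 0 calls therefore do not measure false calls. In simulated data, where fewer genes changed than were called here, 2-fold changes were mostly missed. The comparison of 5' leaders was not run.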

Other observations

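The tests of depth, counted region and uniform response for the -GLU replicate 3 libraries and the test of carried-over reads were chosen after the results were seen, and the tests of low counts, overlapping genes and coding length before. Chaperones were not called as a list in footprints, with 9 up, 10 down and 11 of 30 not called. Single members went either way. SSA2, a cytosolic Hsp70, fell from 3144 ± 143 to 94.0 ± 23.9 CPM, and SSB1, a ribosome-associated Hsp70 with a near-identical copy, from 2529 ± 151 to 34.0 ± 20.8 CPM. The small heat shock genes HSP42 and HSP26 rose by 4.34 ± 0.41 and 6.17 ± 1.07 (edgeR, adjusted p = 9.85e-05 and 0.00165), HSP26 by 4.32 to 6.64 with 1 library left out. In nitrogen and sterol metabolism, GDH1, glutamate dehydrogenase, fell by 4.33 ± 0.27 and ERG12, mevalonate kinase, by 1.96 ± 0.19. CIT1, citrate synthase, went from 96.0 ± 15.2 to 3736 ± 1007 CPM and QCR10, of the cytochrome bc1 complex, from 82.3 ± 4.76 to 1030 ± 208. TSL1, of trehalose synthesis, went from 25 ± 11 to 918 ± 142 CPM. Among genes upstream of filamentous growth, the mucin MSB2 fell by 3.12 ± 0.36 and GPA2, the G protein alpha subunit of glucose sensing, rose by 2.29 ± 0.25.

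In RNA, the regulators of non-fermentable carbon use ADR1 and CAT8 rose by 5.58 ± 0.29 and 5.83 ± 0.34, NDE2, an external NADH dehydrogenase, by 6.74 ± 0.41 and GLC3, the glycogen branching enzyme, by 4.84 ± 0.36. The other -GLU library without cycloheximide, set against the +GLU one, had medians of -5.36 for ribosomal proteins, -3.53 for glycolysis and -1.34 for ergosterol, and of 1.09 for filamentous growth and 1.48 for protein kinase A, with no replicate check. Across genes the fast-harvest -GLU library correlated with -GLU footprint replicates 1, 2 and 3 at Spearman rho 0.960, 0.936 and 0.831, and the other at 0.910, 0.913 and 0.803.

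The -GLU replicate 3 libraries stood apart from -GLU replicates 1 and 2, with PCK1 footprints at 122.5 CPM against 23120 and 9027. Their deviations were shared between assays (Spearman rho 0.57 across 5363 genes), with histones in footprints at a median of 1.53 and ergosterol genes at -1.32. The longer counted region can only add counts, yet 236 of 3355 genes of at least 1000 nt were at least 2-fold lower in -GLU RNA replicate 3 than in both others (68 were higher), which argues against it as the whole cause, although shorter genes did lie higher in that library (rho -0.28 with coding length), the direction it predicts. Lower depth did not account for it, since replicates 1 and 2 thinned to 2391712 counts correlated 0.0898 better with each other than with replicate 3 (0.966 against 0.876), nor did a uniformly smaller response, since 585 of 869 genes changed at least 4-fold in the others (67.3%) went beyond both of them. A difference in culture state or in time without glucose may account for the pattern and was not tested, since the labels give no duration.

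Of 509 genes that rose in efficiency, 91 had under 2 CPM of +GLU footprints, and 88 of these had at least 2 CPM of +GLU RNA. Whether too few counts account for it stays open. With the +GLU count at its upper 95% Poisson bound 91 of 91 (100%) kept a rise of over 1 on the log2 scale (median 2.67), but the genes had been chosen for their call, so this test decides nothing. Carried-over -GLU reads did not account for most of these genes. Their median +GLU to -GLU RNA ratio (58.9%) was 1589 times the lowest among 115 abundant transcripts (0.0371%, RGI2). For members strongly induced in RNA, such as ADY2 (0.127%), ICL1 (0.205%) and POT1 (0.357%), the ratio lay much nearer that value, and carry-over stays open. Of the genes with an annotation, 1.12% (1 of 89) overlapped another coding sequence, against 1.64% of other genes. Antisense or otherwise untranslated transcripts counted as the gene, which the unstated use of strand leaves open, and translation held back with glucose may both account for the pattern, and neither was tested.

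Ribosomal proteins were lower in the other -GLU library than in the fast-harvest one, both without cycloheximide. Short coding sequences went with lower ratios in general (Spearman rho 0.56 across 4881 genes, median -0.78 under 400 nt and 0.49 from 1500 nt), and ribosomal proteins have a median coding length of 441 nt. Set against the 50 genes nearest in coding length, 116 of 125 were still lower, by a median of -1.21, which argues against length as the whole cause. Ribosome run-off during a slower harvest may account for the rest, and was not tested with 1 library each.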
